A study of Mus musculus with 6 samples.

How the data were processed

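RNA was measured in AT2 cells of adult mice of mixed strain background, with 3 Abca3 cKO and 3 control libraries. Per the labels' protocols, AT2 cells were purified by depletion of other cells, total RNA was isolated with RNeasy Plus columns, amplified with the NuGEN Ovation RNA-Seq System v2 and made into Nextera XT libraries. This amplification does not mark the strand of a transcript, so reads of overlapping genes on opposite strands cannot be told apart. The series' design places both groups 6 days after tamoxifen, and the treatment label can also be read as 6 days of tamoxifen. The labels name neither the Cre line, the genotype of the controls nor the deleted exons.

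The deposited counts are whole numbers of reads per gene, not normalized. The authors also deposited RPKM, reads scaled by transcript length and depth. The counts are of amplified material and are not counts of single molecules. The submitters' processing notes name Bowtie2 2.1.0, TopHat2 2.0.8, Cufflinks 2.0.2, DESeq and the mouse build mm10 (GRCm38), without saying which tool made which value. The read counter, its treatment of strand and shared reads, and the gene annotation are not given in the sources used here. Counts and RPKM can part widely: Scgb1a1 was listed at RPKM 0 in Abca3 cKO replicate 1 and control replicate 2, where it had 1776908 and 1943980 counts, and 33 to 47 genes per library with at least 100 counts were listed at RPKM 0. Across the 23415 genes in both tables, the correlation of log2 CPM with log2 RPKM was 0.872 to 0.884 within a library. Counts were therefore the main measure and RPKM an alternative. A separate deposited sheet of counts for 29 symbols was not used. Depth was 23531330 to 26071229 counts per library. Within each group no library repeats the counts of another (chi-square per degree of freedom 30.5 to 52.1 over genes with at least 10 counts). This does not show separate animals, since libraries amplified separately from 1 RNA also differ, and each library was counted as a sample because the labels number it as a replicate.

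Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, which left 14477 of 23478, libraries were scaled by TMM, and the groups were compared by the quasi-likelihood F test (glmQLFit with robust estimation, glmQLFTest, two-sided, group as the only term). P-values were adjusted by Benjamini-Hochberg, and a gene was called at an adjusted p under 0.05. The SE of a log2 fold change is its size divided by the square root of F, and intervals are 95%. They cover the spread between these libraries. Levels are CPM on the TMM-scaled library sizes. Abca3 was also compared by an exact permutation test of log2 CPM, two-sided, whose smallest p is 0.1. Gene lists were tested with fry of limma 3.58.1 on log2 CPM (prior count 2) for the 26 of 29 lists with 5 or more tested members, adjusted over those lists. Fry does not compare a list with other genes. Camera, which does, was run with a preset correlation of 0.01 and with an estimated correlation. The preset called 9 lists, and none of these calls held with an estimated correlation. The lists overlap: 5 of the 30 AT2 genes and 6 of the 22 transitional epithelium genes stand on another list. Coordinates, exon overlaps, GC content and transcript length came from GENCODE M21 on GRCm38, the build that the notes name, and 94.5% of the tested genes and all 55 called genes had a match there. Of the 55, 12 share exon sequence with another annotated gene.

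The groups, the gene lists, the tests, most alternatives and the rule for named genes were set before the data were examined. The rule named Abca3; the 12 higher and 12 lower called genes with the largest fold change, among those with a mean of at least 5 CPM and no overlap between groups, leaving out predicted, Rik, small RNA, ribosomal and mitochondrial symbols; up to 4 members with the smallest p in each list, of which the text gives those that bear on a count; and up to 3 members by level of each list of another cell type, of which the text gives some. It skipped 1 called gene, 9530077C05Rik. Called genes named outside the rule are said to have been chosen after their values were seen. Some genes that were not called also stand outside the rule without that remark, such as Krt8, Hbegf, Etv5, Nfkbia and Hsp90b1. A further result is not reported here.

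The test was tried on simulated data for this comparison, with counts of 14477 genes drawn from the real means and library sizes and 200 genes changed. It called 40% of 50 genes changed 1.5-fold, 72% of those changed 2-fold and 100% of those changed 3-fold or 4-fold, and 12 unchanged genes. With no gene changed it called 0. A list of 30 genes raised 1.5-fold was called by fry and 0 of 20 other lists were. The changed genes and the raised list were drawn from genes with a mean of at least 5 CPM, so these shares do not cover genes with lower counts. Genes were simulated independently of each other, so the lists do not show how fry behaves where genes are correlated.

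Alternatives were scaling by DESeq2's size factor method or by library size alone, no count filter or at least 5 CPM in 3 libraries, the replicate number as a block, each library left out in turn, DESeq2 1.42.0, limma-voom with quality weights, and limma on log2(RPKM + 1) or log2(RPKM + 0.1) with a mean RPKM of at least 0.5, or with no filter. Other thresholds were adjusted p under 0.01 and 0.1, and a 2-fold minimum. An offset for GC content and transcript length (loess, span 0.3) was added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.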

Results

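Alveolar type 2 (AT2) cells are the lung epithelial cells that make, store and secrete pulmonary surfactant, and Abca3 encodes the transporter that moves phospholipid into their lamellar bodies. Messenger RNA was measured by RNA sequencing in AT2 cells purified from adult mice with a conditional deletion of Abca3 (Abca3 cKO, n = 3) and from control mice (n = 3), 6 days after tamoxifen. The series asked how these cells differ after loss of Abca3, in a study of injury and regeneration of the alveolus. The deposited table held 23478 genes, and the total count per library ran from 23531330 in control replicate 1 to 26071229 in control replicate 2. The 3 Abca3 cKO libraries held 23667614, 26052953 and 25037698 counts, and control replicate 3 held 24665397. The labels do not say that replicates came from separate animals, so p-values measure the spread between these samples. Levels are CPM on library sizes scaled by TMM, given as mean ± SD with n = 3 per group, and fold changes are Abca3 cKO over control.

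The libraries were rich in surfactant transcripts. Slc34a2, a phosphate transporter of AT2 cells, stood at 19820 ± 986 CPM in controls, Sftpc at 22507 ± 4006 CPM, Sftpa1 at 14077 ± 602 CPM and Sftpb at 6953 ± 794 CPM. The most abundant transcript was nevertheless Scgb1a1, the main secretory protein of club cells, at 67103 ± 8267 CPM in controls and 60835 ± 13498 CPM in Abca3 cKO (log2 fold change −0.14, adjusted p = 0.877 by edgeR's quasi-likelihood test). Scgb1a1 took 4.76% to 7.51% of all counts in a library, and Lars2, a mitochondrial leucyl-tRNA synthetase gene, took 3.95% to 5.33%. Correlations of log2 CPM between libraries, across genes, ran from 0.958 to 0.968. Control replicate 2 stood apart in sex-linked genes. Xist, the noncoding RNA of the inactive X chromosome, was at 2345 CPM there and at 5.36 to 9.36 CPM in the other 5 libraries, while the Y-linked genes Ddx3y, Kdm5d and Eif2s3y had 0 counts there. The labels give no sex.

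Abca3 itself (chromosome 17, 24351950 to 24410201, plus strand, GRCm38) was 11.3% lower in Abca3 cKO. It stood at 596 ± 22.0 CPM against 672 ± 32.8 CPM in controls, a log2 fold change of −0.17 (SE 0.109), and the 95% interval of the ratio ran from 75.5% to 104%. The 3 Abca3 cKO libraries, at 571, 611 and 606 CPM, all lay below the controls, at 635, 694 and 689 CPM. The difference did not pass edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.696), and the exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 samples allow. On the deposited RPKM scale Abca3 stood at 57.2 ± 2.31 against 71.5 ± 4.79 in controls. Each count sums reads over the whole gene and the labels do not say which exons were deleted, so the level does not check the genotype labels. Exons of Abca3 overlap the gene D330041H03Rik, which stood at about 1.09 CPM in Abca3 cKO but was listed at RPKM 65.6 to 76.2 there and 60.3 to 87.1 in controls.

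**Figure D1:**
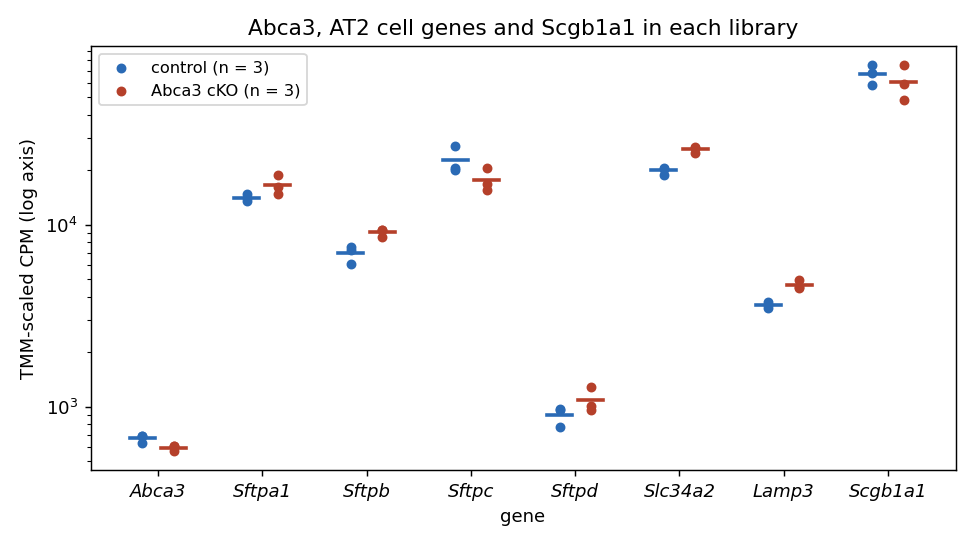
TMM-scaled CPM on a log axis of Abca3, AT2 cell genes and Scgb1a1 in each of the 3 control and 3 Abca3 cKO libraries, with points for libraries and bars for group means. The 3 Abca3 values of the cKO group lie from 571 to 611 CPM, below the 3 controls at 635 to 694 CPM, and none of these genes passed adjusted p 0.05.

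Of 14477 genes tested with edgeR, 55 differed between Abca3 cKO and control AT2 cells, 38 higher and 17 lower. The genes that rose included Rerg, Itih4, Hdc, Lrg1 and Lcn2, and the EGF receptor ligand Areg, the transcription factor genes Myc and Maff and the inflammatory enzyme gene Ptgs2 were among those that fell. In all 55 the values of the groups did not overlap, against 14.1% of the genes tested and the 10% that chance gives for 3 against 3. The median absolute log2 fold change of the 55 was 0.99, and 27 changed at least 2-fold, 17 of them higher and 10 lower. At an unadjusted p under 0.05 there were 1336 genes, with 724 expected by chance. The count depended on single libraries: it was 26 without Abca3 cKO replicate 1, 27 without Abca3 cKO replicate 2 and 21 without control replicate 1, of which 24, 23 and 18 were among the 55. The deposited RPKM values gave 15 genes with limma, 13 of them shared, and DESeq2 on the counts gave 233, which included all 55.

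Among the genes that rose, Itih4 (chromosome 14, 30886476 to 30902353), which encodes an acute-phase plasma protein, stood at 970 ± 59.8 CPM in Abca3 cKO against 352 ± 71.6 CPM in controls (log2 fold change 1.46, SE 0.147, adjusted p = 0.000307). Lcn2 (chromosome 2, 32384633 to 32388252), the siderophore-binding lipocalin, rose from 386 ± 35.0 to 985 ± 23.99 CPM (log2 fold change 1.35, SE 0.115, adjusted p = 7.51e-05). The secreted glycoprotein gene Lrg1 (chromosome 17, 56119678 to 56122001) rose from 190 ± 31.9 to 485 ± 75.3 CPM. Chil1, a chitinase-like secreted protein (chromosome 1, 134182176 to 134190181), rose from 943 ± 131 to 2208 ± 503 CPM. Hdc, which makes histamine from histidine (chromosome 2, 126593667 to 126619299), rose from 138 ± 23.4 to 365 ± 51.3 CPM. Apoc1, an apolipoprotein (chromosome 7, 19689481 to 19692660), rose from 40.0 ± 5.09 to 101 ± 9.91 CPM. The largest rise among the genes named by size was in Rerg, a RAS-like gene known as a target of oestrogen (chromosome 6, 137054825 to 137170497), from 4.53 ± 2.17 to 23.4 ± 3.99 CPM, a log2 fold change of 2.37 (SE 0.312). These 7 genes passed adjusted p 0.05 by edgeR in each of the 6 fits that left out 1 library.

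The other 5 of the 12 risen genes named by size had log2 fold changes from 1.15 to 1.21. They were Vgll3, a cofactor of TEAD transcription factors, the kinase gene Pim1, the membrane protein gene Nnat, the laminin receptor subunit Itga7 and the procollagen protease Bmp1. Each lost its call in at least 4 of the 6 fits that left out 1 library, and Itga7, Nnat and Pim1 share exon sequence with another annotated gene. Other called genes are given here as values only and were chosen after these were seen. Soat1, which makes cholesteryl esters, rose from 498 ± 34.6 to 856 ± 111 CPM. Scp2, a sterol carrier protein, rose from 199 ± 17.6 to 315 ± 7.56 CPM, and the lipoprotein-associated esterase Pon1 rose from 80.1 ± 14.2 to 146 ± 27.4 CPM. Lrp2, the endocytic receptor megalin, rose from 1525 ± 85.7 to 2702 ± 167 CPM.

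Among the genes that fell, Areg (chromosome 5, 91139599 to 91148432), which encodes the EGF receptor ligand amphiregulin, went from 29.97 ± 3.52 CPM in controls to 6.13 ± 0.709 CPM in Abca3 cKO (log2 fold change −2.29, SE 0.184, adjusted p = 7.36e-05). Areg was also the only gene named by size that stayed past adjusted p 0.05 in all 17 alternative analyses. Tnip3, an inhibitor of NF-kB signalling (chromosome 6, 65525313 to 65634040), had the lowest fold change, from 11.1 ± 4.63 to 1.58 ± 0.179 CPM (log2 fold change −2.81, SE 0.345). The gene beside it, Ndnf, which encodes a secreted glycoprotein (chromosome 6, 65671590 to 65712326), went from 600 ± 106 to 250 ± 42.0 CPM. Thbs1, the matrix protein thrombospondin 1 (chromosome 2, 118111876 to 118127133), fell from 144 ± 34.2 to 58.4 ± 9.02 CPM, and shares exon sequence with a predicted gene. Srxn1, the sulfiredoxin that repairs oxidised peroxiredoxins (chromosome 2, 152105516 to 152111376), fell from 50.1 ± 11.9 to 19.7 ± 2.76 CPM. Maff, a small MAF transcription factor (chromosome 15, 79346621 to 79359076), fell from 41.8 ± 4.50 to 19.0 ± 2.62 CPM. Arl4c, a small GTPase (chromosome 1, 88673125 to 88702221), fell from 111 ± 10.7 to 55.8 ± 6.97 CPM. All of these kept their call in each of the 6 fits without 1 library. The calls of Myc, Lgals3, Ptgs2, the GTPase gene Rasd2 (log2 fold change −1.28) and the anion exchanger Slc26a4 (−1.17) did not, each being lost in at least 4 of those fits. Myc stood at 5.33 ± 1.48 CPM against 14.9 ± 5.22 CPM in controls, and the galectin gene Lgals3 at 15.7 ± 2.22 against 31.3 ± 7.80 CPM. The cyclooxygenase genes moved apart: Ptgs2 fell from 97.2 ± 25.5 to 49.0 ± 8.05 CPM, while Ptgs1, chosen after its values were seen and sharing exon sequence with a predicted gene, rose from 204 ± 23.95 to 376 ± 17.2 CPM.

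**Figure D2:**
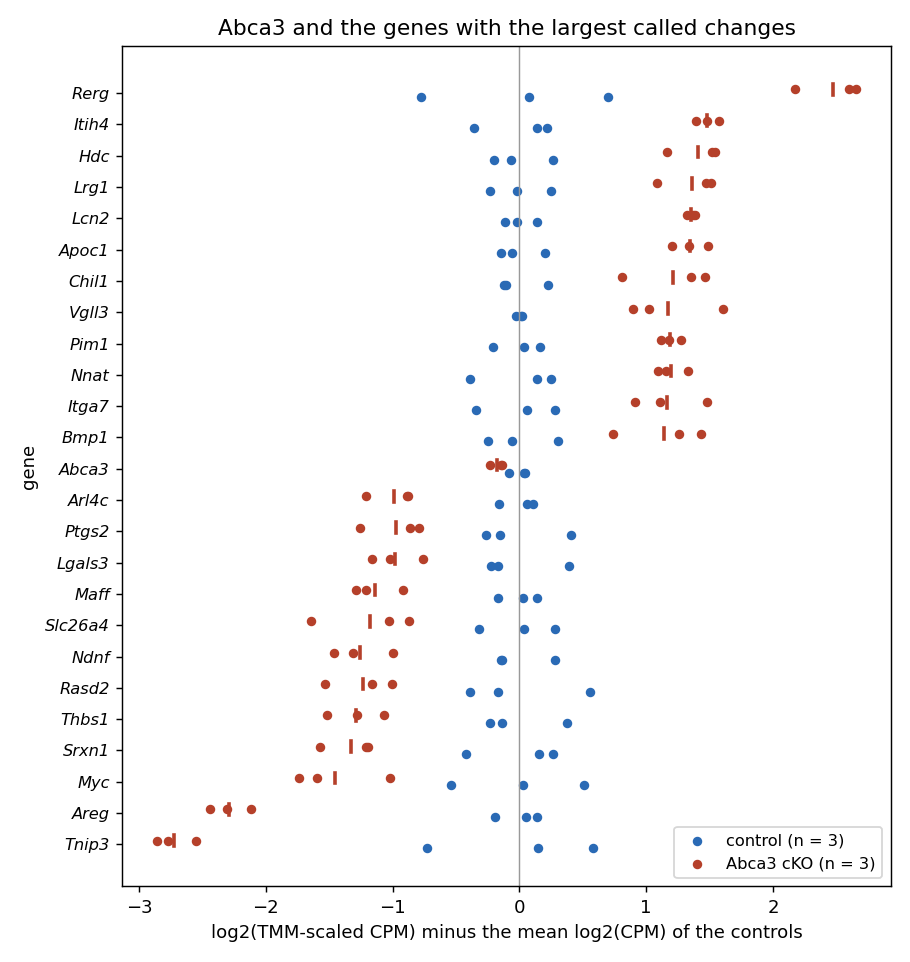
Log2 TMM-scaled CPM of each library minus the control mean of log2 CPM, for Abca3 and the 12 higher and 12 lower genes with the largest called fold changes, with points for the 3 libraries of each group and short bars for the mean of the Abca3 cKO libraries. Apart from Abca3, every gene drawn passed adjusted p 0.05, and Tnip3, with a log2 fold change of −2.81, and Rerg, with 2.37, mark the ends of the range.

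Genes were then grouped by 29 lists fixed before the data were examined, of which 26 had at least 5 tested members. Each was tested with fry, which asks whether the genes of a list move on balance in a single direction, and 1 list passed an adjusted p of 0.05 while 4 had an unadjusted p under 0.05. That list held antioxidant and NRF2 target genes, which moved down (18 tested, median log2 fold change −0.21, fry adjusted p = 0.0258), a call that camera with an estimated correlation did not make (adjusted p = 0.549). In it 6 genes had an unadjusted p under 0.05, 5 of them lower, and DESeq2 called 2. With edgeR 1 gene fell over all genes tested, Srxn1, and 3 fell when adjusted over the list alone, which added Gclm, a subunit of the enzyme that starts glutathione synthesis, and G6pdx, which supplies NADPH. Gclm stood at 19.3 ± 1.19 against 29.2 ± 1.70 CPM and G6pdx at 103 ± 10.5 against 134 ± 15.5 CPM. The fall did not extend to every member, since catalase (Cat) had a log2 fold change of 0.32 (SE 0.119, adjusted p = 0.392). The call was lost without Abca3 cKO replicate 1 (adjusted p = 0.127), Abca3 cKO replicate 2 (0.190), control replicate 1 (0.0732) or control replicate 2 (0.278). It was also lost on the RPKM values (0.164 to 0.191), and over all alternatives it ran from 0.00342 to 0.549. By fry's other test, of change in either direction, 12 of the 26 lists passed. These were the antioxidant, AT2 identity, transitional epithelium, TGF-beta, EGF, FGF and Wnt, NF-kB, p53, interferon and macrophage lists. The lists of phospholipid synthesis, fatty acid synthesis and sterol efflux were also among them.

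The AT2 identity and surfactant list had 5 of its 30 members higher and none lower over all genes tested with edgeR, and 12 higher and 1 lower when adjusted over the list alone, while 18 had an unadjusted p under 0.05, 16 of them higher, DESeq2 called 9 and fry gave an adjusted p of 0.0692. The 5 were Lcn2, Itih4, Chil1, Napsa, the protease that processes surfactant protein B (chromosome 7, 44572380 to 44586862; 522 ± 39.0 against 330 ± 29.7 CPM), and the alarmin Il33 (704 ± 141 against 351 ± 69.6 CPM). The calls of Napsa and Il33 were each lost in at least 4 of the 6 fits without 1 library, and Napsa shares exon sequence with another annotated gene. Of the 30 log2 fold changes 26 were positive, with a median of 0.31. The surfactant protein genes themselves did not pass: Sftpb had a log2 fold change of 0.38 (adjusted p = 0.303), Sftpa1 0.23 (adjusted p = 0.648), Sftpd 0.26 (adjusted p = 0.630) and Sftpc −0.36 (adjusted p = 0.479). Beside these genes, markers of alveolar type 1 (AT1) cells leaned the other way. None of the 17 AT1 markers passed over all genes tested with edgeR, 6 were lower when adjusted over the list alone, the median log2 fold change was −0.35 and fry gave an adjusted p of 0.491, while 6 had an unadjusted p under 0.05 and DESeq2 called 3. Akap5 stood at 520 ± 101 against 771 ± 75.1 CPM and Clic5 at 583 ± 116 against 887 ± 147 CPM.

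Genes of the transitional state that alveolar epithelium enters after injury included 3 that fell, Areg, Tnip3 and Lgals3, and 1 that rose, Lcn2, among 22 tested. Adjusted over the list alone, 11 were lower and 2 higher. Among the lower was Krt8, the keratin that marks this state, at 51.8 ± 3.74 against 72.1 ± 2.22 CPM (adjusted p = 0.127 over all genes). Krt8 stands outside the rule for named genes. The median log2 fold change was −0.42 and fry gave an adjusted p of 0.136, while 14 had an unadjusted p under 0.05, 12 of them lower, and DESeq2 called 7. Of 17 genes of the TGF-beta pathway only Thbs1 fell with edgeR, adjusted over the list alone as well, while 7 had an unadjusted p under 0.05, all lower, and DESeq2 called 1. The median log2 fold change was −0.22 with 3 of 17 positive, and the fry adjusted p was 0.277. Of 24 genes of EGF, FGF and Wnt signalling, Areg and Myc fell and none rose with edgeR at its main settings (9 had an unadjusted p under 0.05, 4 of them higher, and DESeq2 called 4), while adjusted over the list alone 3 fell, with Hbegf added, and 3 rose, Fgf7, Lrp5 and Etv5. Fgf7 had a log2 fold change of 0.76 (adjusted p = 0.0536 over all genes), and edgeR without a count filter called both Fgf7 and Lrp5 higher, as did DESeq2. The fry adjusted p was 0.918. Among 14 cytokine, chemokine and NF-kB genes, Lcn2 and Il33 rose, and Ptgs2 and the chemokine Cxcl16 fell (5 had an unadjusted p under 0.05 and DESeq2 called 4). Cxcl16 shares exon sequence with another annotated gene. Adjusted over the list alone Nfkbia joined the lower genes, and the fry adjusted p was 0.491. The mean log2 fold change of this list was 0.02 while its median was −0.14 and its tested direction was down.

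Genes of lipid synthesis showed few calls. Over all genes tested with edgeR, none passed among 33 genes of phospholipid synthesis (9 had an unadjusted p under 0.05 and DESeq2 called 1), 25 of cholesterol synthesis (3 and 1), 26 of fatty acid synthesis (8 and 1) and 26 of fatty acid oxidation (1 and 0). Adjusted over the list alone, Lpin2, a phosphatidate phosphatase, was lower at 335 ± 77.8 against 582 ± 114 CPM. Elovl1, which elongates very long chain fatty acids, was higher at 1003 ± 138 against 622 ± 107 CPM, and Acsl3 was lower at 49.5 ± 6.89 against 68.3 ± 4.58 CPM. In the cholesterol list 3 of 25 log2 fold changes were positive and the median was −0.21. The fry adjusted p was 0.491 for phospholipid synthesis, 0.538 for cholesterol synthesis, 0.733 for fatty acid synthesis and 0.831 for fatty acid oxidation. By fry's test of change in either direction, phospholipid synthesis (adjusted p = 1.15e-05) and fatty acid synthesis (0.00349) passed, as did sterol efflux (0.00042). Cholesterol synthesis and fatty acid oxidation did not (0.409 for each). In all, 12 of the 26 lists passed this test, which does not compare a list with other genes. Of the 14477 genes tested with edgeR, 1336 had an unadjusted p under 0.05. At an unadjusted p under 0.05, phospholipid synthesis had 3 genes higher and 6 lower, and fatty acid synthesis 4 higher and 4 lower. Among 11 genes of sterol efflux only Apoc1 rose with edgeR, adjusted over the list alone as well (3 had an unadjusted p under 0.05, DESeq2 called 1, fry adjusted p = 0.456), and Abca1, the cholesterol exporter, had a log2 fold change of −0.34 (adjusted p = 0.360). Of 19 other ABC transporter genes none passed with edgeR, over all genes or adjusted over the list alone (3 had an unadjusted p under 0.05, DESeq2 called 0, fry adjusted p = 0.831). Their median log2 fold change was 0.06 while the tested direction was down.

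Stress and housekeeping lists also held few calls. Of 25 genes of the unfolded protein response none passed over all genes with edgeR (8 had an unadjusted p under 0.05 and DESeq2 called 0). Adjusted over the list alone 5 chaperone genes were higher, Hspa5, Hsp90b1, Hyou1, Pdia4 and Sdf2l1, with Hspa5 at 704 ± 166 against 501 ± 28.98 CPM. Fry gave an adjusted p of 0.322 for this list, and 0.0170 without Abca3 cKO replicate 3, in a range from 0.0170 to 0.634 over the alternatives for the unfolded protein response. None of 27 lysosome and autophagy genes passed over all genes with edgeR (3 had an unadjusted p under 0.05 and DESeq2 called 1, fry adjusted p = 0.834), and the cholesterol-binding protein gene Npc2 was higher when adjusted over the list alone, at 1965 ± 273 against 1397 ± 53.8 CPM. Among 16 p53 targets the kinase gene Plk2 was lower adjusted over the list alone, at 22.8 ± 2.62 against 37.0 ± 4.14 CPM, and none passed over all genes (3 had an unadjusted p under 0.05, DESeq2 called 1, fry adjusted p = 0.831 for a direction of down against a median of 0.06). Among 20 immediate early and heat shock genes, which tissue dissociation also induces, none passed over all genes (4 and 1, fry adjusted p = 0.491), while Klf6 was lower and Socs3 higher when adjusted over the list alone. No gene passed, over all genes or adjusted over the list alone, among 22 genes of the respiratory chain (0 had an unadjusted p under 0.05 and DESeq2 called 0, fry adjusted p = 0.831), 33 of the cell cycle (3 and 0, 0.993) or 23 of the interferon response (3 and 0, 0.715). The same held for 8 genes of MHC class II antigen presentation (2 and 0, 0.831). Within the class II list H2-Eb1 (log2 fold change −1.94, adjusted p = 0.651) was uneven between libraries, at 2.57, 1.87 and 15.5 CPM in Abca3 cKO replicates 1, 2 and 3 against 23.2 to 27.5 CPM in controls. Without Abca3 cKO replicate 3 its log2 fold change was −3.52 (adjusted p = 6.34e-05), and its adjusted p in the other alternatives ran from 0.151 to 0.851.

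Markers of other cell types were measured because the cells were purified by depletion. Hdc, which is also made by neutrophils and stood on their list, rose, while the neutrophil receptors Cxcr2 and Csf3r had log2 fold changes of −0.19 and 0.02 (adjusted p = 0.868 and 0.990). On the RPKM scale Cxcr2 was listed at only 0.22 to 0.53 and Csf3r at 0.03 to 0.19, against 34.5 to 118 for Hdc. The counts of the 2 receptors may therefore say little about neutrophils. Apart from Hdc, no marker on these lists passed over all genes with edgeR. Mesenchymal genes had positive log2 fold changes in 18 of 20 (median 0.37, fry adjusted p = 0.324, 8 with an unadjusted p under 0.05, 1 called by DESeq2), and 6 were higher adjusted over the list alone, with Col1a1 at 96.0 ± 10.3 against 64.7 ± 17.2 CPM. Of 9 macrophage markers Plet1 was lower adjusted over the list alone, at 39.9 ± 1.16 against 56.4 ± 3.17 CPM (fry adjusted p = 0.491, 1 with an unadjusted p under 0.05, 1 called by DESeq2). None of 13 endothelial, 17 club and ciliated, or 10 basal, neuroendocrine and mesothelial markers passed even when adjusted over the list alone. Each of these 3 lists had 2 genes with an unadjusted p under 0.05 and 0 called by DESeq2, and the fry adjusted p was 0.831, 0.831 and 0.491. Lymphocyte, neutrophil and erythroid lists had 2, 4 and 1 tested members, too few for a list test. In Abca3 cKO, Bgn of mesenchyme stood at 589 ± 107 CPM, Kdr of endothelium at 57.7 ± 21.6 CPM and Csf1r of macrophages at 41.2 ± 9.95 CPM. Cd79b of lymphocytes stood at 7.63 ± 1.07 CPM and Upk3b of mesothelium at 188 ± 82.1 CPM.

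**Figure D3:**
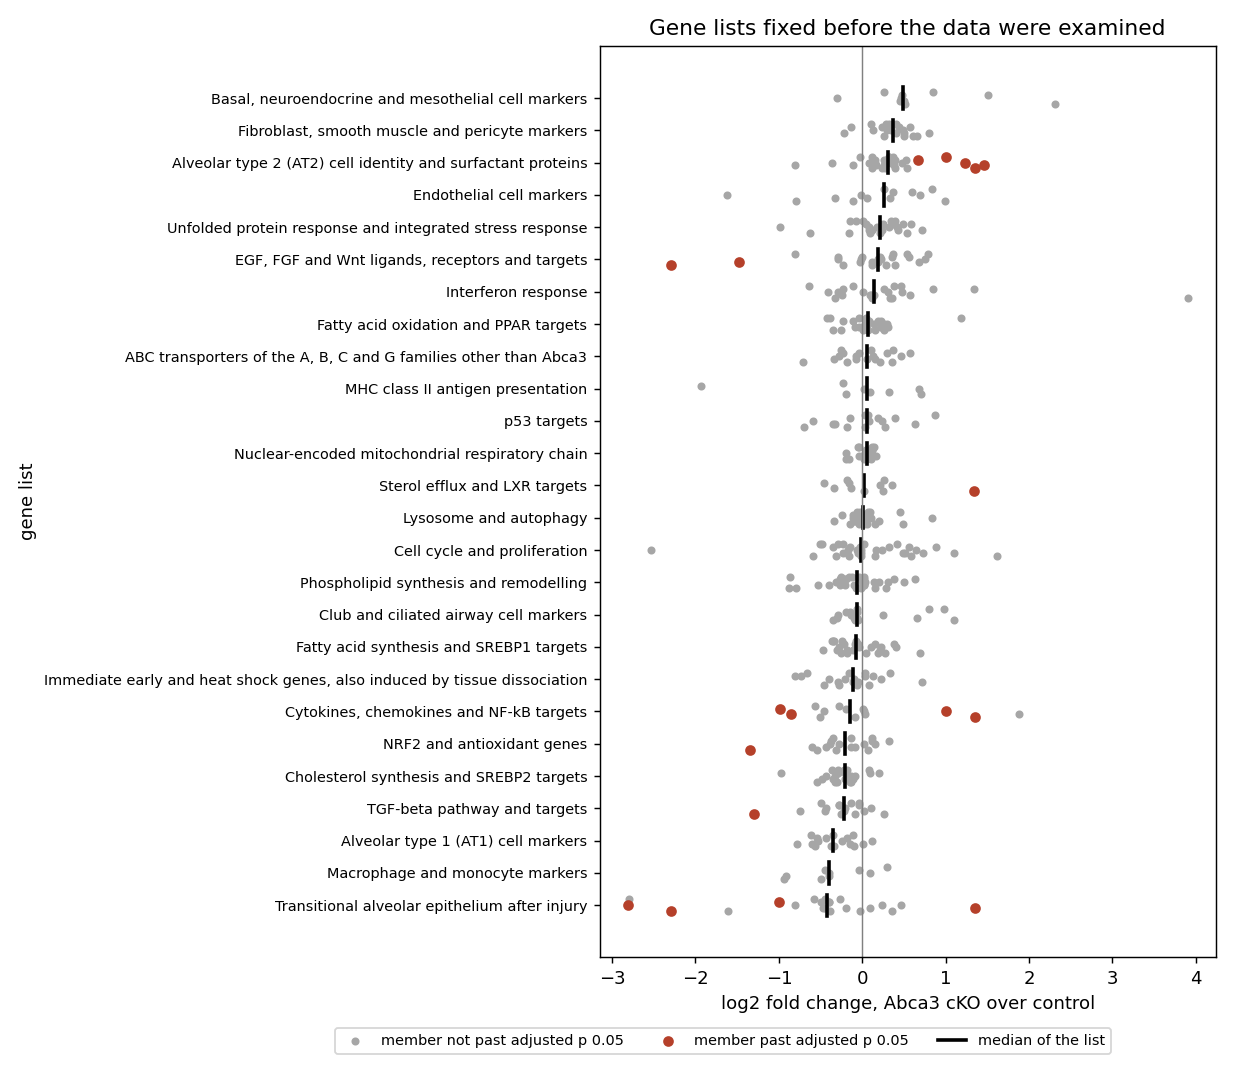
Log2 fold change of Abca3 cKO over control for each tested member of the 26 gene lists with at least 5 tested members, drawn as points in list order of the median, with red points for members past adjusted p 0.05 over all genes and black bars for list medians. Of the medians the transitional epithelium list has −0.42, the AT1 list −0.35, the antioxidant and NRF2 list, the only 1 called by fry (not by camera with an estimated correlation, nor in 4 of the 6 fits without 1 library), −0.21, and the AT2 list 0.31.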

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

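The GC content and length offset was chosen after seeing the data. Of the 55 genes by edgeR, scaling by DESeq2's size factors kept all 55, library size alone gave 48 and a minimum of 5 CPM gave 70. Without a count filter there were 132, with DESeq2 233 (85 of them lower), with limma-voom 66 and with the offset 52. On RPKM, limma gave 15 genes at a pseudocount of 1, 13 at 0.1 and 2 without a filter, which shared 13, 11 and 1 with the 55. The cause was not tested. Stricter and looser thresholds gave 21 genes at adjusted p under 0.01, 99 under 0.1 and 27 with a 2-fold minimum. Leaving out 1 library, which also leaves fewer samples, gave 21 to 50 genes, with 21 without control replicate 1, 26 without Abca3 cKO replicate 1 and 27 without Abca3 cKO replicate 2. Abca3 had negative log2 fold changes throughout, from −0.32 to −0.15 over 17 alternatives (−0.21 to −0.15 without 1 library), and adjusted p from 0.433 to 0.883. The 1 list by fry stayed at 1 under other scalings and filters. It became 0 on RPKM at either pseudocount or without a filter, 0 with the offset (adjusted p = 0.0960), and 0 to 2 without 1 library. With camera it became 9 at the preset correlation and 0 at an estimated one. The cause was not tested. For the antioxidant list the adjusted p over all alternatives ran from 0.00342 to 0.549. The libraries do not show a pairing by replicate number: deviations of same-numbered libraries correlated at 0.0762, −0.0304 and −0.0272 across genes, and not every library correlated best with its own number. With 3 libraries per group these correlations cannot exclude a pairing. With the replicate number as a block there were 33 genes, 30 of them among the 55, and 0 lists, and the adjusted p of the antioxidant list was 0.201. Over 118 other named genes, calls were the same in 325 and weaker in 134 comparisons of called genes, 29 comparisons of uncalled genes became called, and no called gene changed sign. At these depths and with 3 samples per group, 40% of 1.5-fold changes in genes with a mean of at least 5 CPM were called in simulated data. Depth itself was not varied.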

Other observations

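The tests of AT2 cell share, of the calls without control replicate 2, of a GC and length bias and of a segment around H2-Eb1 were chosen after the results were seen: the share test's prediction was written after its list had been examined, that of the calls without control replicate 2 after these were known, the GC and length offset was an added alternative, and the H2-Eb1 test was added once its levels were known. For the hypotheses at the end, adjustment over the 2 lists was chosen after their p-values had been seen. Several called genes outside the rule for named genes, chosen after their values were seen, stand out. Counts assigned to Esr1, the oestrogen receptor gene (chromosome 10, 4611593 to 5005614), went from 1.51 ± 0.234 CPM in controls to 7.32 ± 1.45 CPM in Abca3 cKO (log2 fold change 2.27, SE 0.318, adjusted p = 0.00453 by edgeR), with 6.42 to 8.99 CPM in the 3 Abca3 cKO libraries and 1.27 to 1.74 CPM in the controls. The labels do not name the Cre line, and counts per gene do not show whether these reads come from the endogenous gene or from a transgene that holds part of its sequence. Isyna1, which makes inositol phosphate from glucose phosphate, rose from 30.9 ± 3.37 to 60.1 ± 4.81 CPM, and the phosphatidylinositol kinase gene Pi4k2b fell to 185 CPM from 359 CPM. The aminopeptidase gene Anpep rose from 618 ± 53.9 to 1101 ± 148 CPM and the copper importer Slc31a1 from 544 ± 47.0 to 839 ± 71.5 CPM, while F2rl1, a protease-activated receptor, fell from 96.5 ± 8.51 to 61.4 ± 5.73 CPM.

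The first pattern is the 55 genes called between the groups. A GC content or length bias is argued against, since with a per-library offset for both 100% of the 55 kept at least 0.8 times their log2 fold change and 87.3% stayed past adjusted p 0.05. Control replicate 2, with its Xist level, is argued against as the source for 33 of the 55, which were among the 46 genes called by the fit that does not use it. The loss of the other 22 calls does not single out this library. The fits without control replicates 1 and 3 called 18 and 35 of the 55 again. Those without Abca3 cKO replicates 1, 2 and 3 called 24, 23 and 30. Without control replicate 2 all 55 kept their sign, and their median log2 fold change was 0.972 times as large. Control replicates 1 and 3 also lay outside the range of the Abca3 cKO values in all 55. All 55 were picked in a fit that used control replicate 2, and in all 55 the groups did not overlap. That fixed the signs and the place of control replicates 1 and 3 beforehand, and limited how far the ratio could fall. These values therefore cannot decide whether control replicate 2 is the source of the 55 as a set. Of the 10 splits of the 6 libraries into 3 and 3, only the real split, 1 of 10, gave as many genes (55, against 7 in the highest other), and only that split, 1 of 10, gave as many lists (1, against 0), but 10 splits cannot give a share under 0.1. Deletion of Abca3 stays open as a biological explanation. It was not tested against other differences between the mice, such as strain background or Cre, or against a different mix of cells in the preparations. Sex, as read from the Xist level of control replicate 2, is argued against for the 33 genes called again without that library. It stays open for the other 22.

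The second pattern is the 5 AT2 identity genes that rose. Lists of other cell types moved apart, with calls of the next 3 by camera at the preset correlation but not at an estimated one or by fry: AT1 markers had a median log2 fold change of −0.35 (2 of 17 positive), mesenchymal markers 0.37 (18 of 20) and basal, neuroendocrine and mesothelial markers 0.49 (9 of 10). A larger share of AT2 cells in the Abca3 cKO preparations would raise all AT2 genes by about the same factor. Of the 30 genes, 63.3% (19) had a 95% interval wholly below the smallest called log2 fold change, 0.66. That bound was taken from members called in these same data, so the percentage alone does not decide. The interval for Sftpc ended at −0.03, where a common rise would not place it. Sftpc is 1 gene of the 30, however, and it did not pass edgeR's test over all genes (adjusted p = 0.479). In Abca3 cKO replicate 3 it stood at 20431 CPM, above control replicates 1 and 2 at 20367 and 20026 CPM. Cell share as the whole explanation is therefore not decided. A smaller shift in share, of the size of the list median of 0.31, is not excluded. A change of expression within AT2 cells after loss of Abca3 stays open.

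The third pattern is H2-Eb1, which lies on the same chromosome as Abca3 (17, 34305867 to 34316674) and was low in Abca3 cKO replicates 1 and 2. The strain background is mixed, and a segment of another strain carried with the Abca3 allele could change genes near it. Genes within 10 Mb of Abca3 had an unadjusted p under 0.05 in 27 of 270 cases against 1256 of 13406 elsewhere, an odds ratio of 1.07 (95% interval 0.691 to 1.61), and only Pim1 among them was called. That argues only against a segment shared by the Abca3 cKO libraries that raises these odds beyond 1.61, and a smaller excess is not excluded. For a segment in Abca3 cKO replicates 1 and 2 alone, genes within 10 Mb of H2-Eb1, itself left out, had an unadjusted p under 0.05 without Abca3 cKO replicate 3 in 35 of 321 cases against 1264 of 13654 elsewhere. The odds ratio was 1.20 (95% interval 0.815 to 1.72), and only Tff2 was called. That argues only against a segment around H2-Eb1 that raises the odds beyond 1.72, and a smaller excess is not excluded. H2-Eb1 lies within 10 Mb of Abca3, so the 2 windows overlap and the tests are not separate. A variant in H2-Eb1 itself is not excluded by this test, and which animals carry which strain's alleles was not tested.

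Two-sided fry tests of 2 further hypotheses used lists written before they were tested and without called genes. The first holds that the lower Areg and Myc may go with lower output of the ERK pathway, for which fry on the list of ERK output genes gave an adjusted p = 0.0367 over the 2 lists, with a median log2 fold change of −0.15 over 16 genes. Support is thin: the values of several members, Ier3, Dusp6, Spry2 and Spry4 among them, had been seen before, 6 of the 16 were positive, among them the feedback genes Dusp6 (0.21) and Spry4 (0.54), none was called, and camera with an estimated correlation did not pass 0.05 for the list. The other holds that Lcn2, Lrg1 and Itih4 may be part of a broader STAT3 and acute phase response. Its list of 19 genes had a median of 0.26 with 15 positive, but fry gave an adjusted p = 0.112, which leaves it undecided. Lbp, a secreted binder of bacterial lipopolysaccharide, came closest to a call there (log2 fold change 0.60, adjusted p = 0.0681).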
